A study of Rattus norvegicus with 6 samples.

How the data were processed

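The deposited table gives 1 value per gene and library for 6 bulk RNA-seq libraries of rat L4 to L6 dorsal root ganglia, and each column was assigned to its group and replicate by its name. The values are expected counts, that is estimated reads per gene that need not be whole, as the authors deposited them: 32.7% of the values were whole numbers and the columns summed to different totals. Per the labels' protocols, RNA was extracted with Trizol from tissue kept in RNAlater, only preparations with a RIN of at least 8.0 were used, and sequencing was on the BGISEQ-500. The genome build named in the submitters' processing notes is Rnor_6.0. The aligner, the counting program, its handling of strand and of reads shared between genes, and the gene annotation are not given in the sources used here.

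The table holds 22864 genes, of which 2907 were blank in every library and were read as 0, and 3441 were at 0 in every library after rounding. Expected counts were rounded to whole numbers before any test. Library totals ran from 18284891 to 19981081, levels are given as CPM (counts scaled to the library total), and the intervals and floors given below cover counting error only. Gene identifiers were looked up in a table of the GRCr8 assembly, a later build than that of the data, for names only: 20690 identifiers matched, 17001 of them with the same symbol, and 14847 of the genes tested matched. No coordinates are given for that reason.

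Expression was tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, with 1 fit of all 6 libraries and group as the only term. The filter was filterByExpr by group (minimum count 10, minimum total count 15), which left 15531 genes, and the scaling was TMM. The fit had 3 residual degrees of freedom, a prior of 3.64 degrees of freedom and a common biological coefficient of variation of 10.3%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Standard errors (SE) are the log2 fold change divided by the square root of F. Levels are given as TMM-scaled CPM, mean ± SD, n = 2 libraries per group. Where a group had no reads of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval.

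In all, 33 gene lists with 808 members, 765 of them in the table, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists cover nerve injury and regeneration, nociceptors, large sensory neurons, ion channels, opioid and other inhibitory receptors, synaptic vesicles, TNF signalling, cytokines, interferon, antigen presentation, complement, inflammasome, oxidative stress, hypoxia, immediate early genes, glucocorticoid targets, proliferation and the nuclear respiratory chain. The remainder are markers of satellite glia, Schwann cell myelin, macrophages, lymphocytes, neutrophils, mast cells, endothelium, pericytes and smooth muscle, fibroblasts and matrix, red blood cells, adipocytes, skeletal muscle, bone and cartilage, and spinal cord cells. The list of mitochondrially encoded genes was not analysed here, which left 32. Each list was tested with camera of limma 3.58.1 on the edgeR data, with a correlation between genes preset at 0.01, two-sided and adjusted over the 32 lists of a comparison. The same test was repeated with the correlation estimated from the data, and fry gave tests of directional and of mixed change.

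The rule took, for each of the first 2 comparisons, the 10 genes with the highest and the 10 with the lowest log2 fold change among those called, and 5 and 5 for the last. Their groups could not overlap, the higher group had to reach 1 CPM, and provisional symbols were left out. Because fewer passed, places were filled with the lowest p in that direction, and such genes are said not to have passed. In each list described, the 3 members with the lowest p were named, and Tnf, Tnfrsf1a and Tnfrsf1b in every comparison. Other genes are marked as chosen after their values were seen.

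Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, no filter or 1 CPM in 2 libraries, only the 2 groups compared, the title number as a block, a robust prior, an absolute log2 fold change of at least 1, an adjusted p under 0.1, and each library left out in turn. With 1 library left out, the lone library of its group is assumed to vary as the other groups do. Added after seeing the data were DESeq2 for the named genes and 3 changes to list membership. Figures were drawn with matplotlib 3.10.9.

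The procedure was tested on simulated data drawn from the real means and totals, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For CPIP+Veh against Sham+Veh (15379 genes) it recovered 38.8% of the genes changed 1.5-fold, 74.6% at 2-fold and 84.8% at 4-fold. For CPIP+ETA against CPIP+Veh (15379 genes) the shares were 52.2%, 70.1% and 97.0%, and for CPIP+ETA against Sham+Veh (15381 genes) 34.3%, 67.2% and 93.9%. Each simulation gave 15 false calls. A simulated list raised 1.3-fold was called in each comparison with either correlation setting, and none of the unchanged lists was, with genes drawn independently of each other.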

Results

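RNA sequencing profiled the ipsilateral L4 to L6 dorsal root ganglia, which hold the cell bodies of the sensory neurons of the hind limb, of male wild-type rats in 3 groups. In the CPIP groups an O-ring was tied around the hind limb near the ankle for 3 h under anaesthesia, a procedure known in the field as the chronic post-ischaemia pain model. Sham rats had the anaesthesia without the ring. Vehicle (Veh) or etanercept (ETA), a soluble TNF receptor fusion protein that binds TNF, was injected intrathecally each day, starting after 2 days, and ganglia were taken on day 7. The groups are Sham+Veh, CPIP+Veh and CPIP+ETA with 2 libraries each, written below as Sham+Veh 1 and 2 and so on. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

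Total counts were 18391771 and 18284891 for Sham+Veh, 19825521 and 19823500 for CPIP+Veh, and 19981081 and 18290231 for CPIP+ETA. Between 17773 and 17921 genes were detected per library, and the 10 most abundant genes took 6.09% to 6.46% of the counts. Pairs of libraries within groups and between groups overlapped in how alike they were. Spearman correlations across genes were 0.9921 to 0.9931 for the 3 pairs within groups and 0.9909 to 0.9933 for the 12 pairs between groups. The first principal component held 25.5% of the variance and placed CPIP+ETA 1 (25.6) and CPIP+ETA 2 (-18.1) far apart. Within groups, libraries differed by more than sampling noise (chi-square per gene 5.99 to 9.97).

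CPIP+Veh was compared with Sham+Veh to find what the ischaemia model changed in the ganglion. Genes that sensory neurons switch on after axon damage rose as a group. Of the 34 measured members of the nerve injury and regeneration list, 26 lay above sham, with a median log2 fold change of 0.39 (limma camera, adjusted p = 1.11e-23, n = 2 libraries per group, but adjusted p = 0.352 with an estimated correlation). At a p adjusted over the list alone, 15 members were higher and 0 were lower. Over all genes tested edgeR called none of them, with 18 at an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. The 3 members with the lowest p were Reg3b, Vip and Stmn4. Reg3b, a secreted lectin induced in injured neurons, had a log2 fold change of 1.92 (SE 0.35). Vip, a vasodilator neuropeptide, was counted 194 times in CPIP+Veh and 1 time in sham, a ratio of 180 (95% interval 31.9 to 7150). Stmn4, a regulator of microtubules, had a log2 fold change of 0.66 (SE 0.12).

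Further members that passed over the list alone were chosen after their values were seen. The transcription factors Atf3, an early marker of axon injury, and Sox11 had log2 fold changes of 2.00 (SE 0.66) and 0.87 (SE 0.20). The neuropeptides Npy and Gal, which appear in injured sensory neurons, had 5.48 (SE 1.4) and 1.20 (SE 0.34), and the growth cone protein Gap43 had 0.35 (SE 0.091). Cacna2d1, the calcium channel subunit bound by gabapentin, had 0.47 (SE 0.09), and the neurotrophin Bdnf 0.58 (SE 0.11). The remaining members that passed were Csrp3, Ecel1, Reg3a, Cckbr and Gadd45a, between 0.49 and 3.57. Levels differed between the CPIP+Veh libraries: Atf3 stood at 16.2 and 42.1 CPM (7.69 and 6.90 in sham), and Npy at 6.08 and 35.8 CPM (0.32 and 0.60 in sham). Without CPIP+Veh 2 the median of the list fell to 0.22, still called, and Atf3 had 1.16, Npy 3.70 and Ecel1 1.31. Npy had 6.25 without CPIP+Veh 1, and Cckbr, at 1.49, had 2.08 without Sham+Veh 2. Of the 45 splits of the 6 libraries into pairs, 2 gave this list a result as strong, both with the CPIP+Veh libraries on one side and 1 of them the real comparison. In 20 splits some list was as strong as this one. Large sensory neuron markers (median -0.04, adjusted p = 0.343) and nociceptor markers (median 0.01, adjusted p = 0.363) did not pass.

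**Figure D1:**
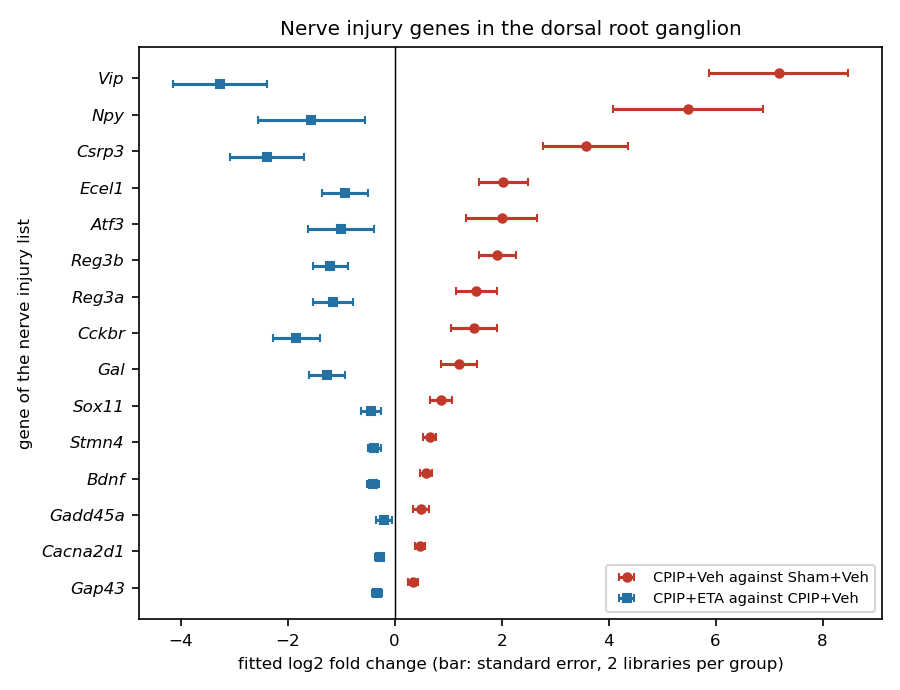
Fitted log2 fold changes (x axis) of the 15 nerve injury genes that passed over the list alone in CPIP+Veh against Sham+Veh (circles), with the same genes in CPIP+ETA against CPIP+Veh (squares); bars are standard errors, with 2 libraries per group. All 15 lie above 0 in the model, from Gap43 (0.35) to Vip (1 read in sham), and below 0 with etanercept; they were picked as higher in CPIP+Veh, whose libraries enter both comparisons, so lower values with etanercept are expected by chance too.

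Genes of antigen presentation rose in CPIP+Veh as well. The list had a median log2 fold change of 0.30 over 24 members (camera, adjusted p = 7.73e-13, adjusted p = 0.352 with an estimated correlation), with 6 members higher and 0 lower adjusted over the list alone. RT1-Ba and RT1-Bb, chains of an MHC class II molecule, had log2 fold changes of 1.46 (SE 0.25) and 1.67 (SE 0.36; 1.05 without CPIP+Veh 2), and the class I gene RT1-A1 0.66 (SE 0.12). Cd74, the class II invariant chain and a further member that passed, had 0.60 (SE 0.15) and was chosen after its value was seen. RT1-CE10, a class I gene outside the list (gene identifier 414792), rose from 24.3 ± 1.2 to 65.6 ± 0.29 CPM (SD, n = 2; log2 fold change 1.43, SE 0.097, edgeR adjusted p = 0.0196). RT1 class I genes are near-identical and can exchange reads, so their single values are uncertain. The summed CPM of 27 RT1 genes was 679 and 645 in sham, 976 and 910 in CPIP+Veh, and 875 and 700 in CPIP+ETA. The 18 class I genes among them summed to 523 and 493, 733 and 560, and 593 and 503 CPM. The 9 class II genes summed to 156.2 and 151.5, 242.6 and 350, and 281.7 and 196.5 CPM, higher in every CPIP library than in sham. The class I light chain B2m had a log2 fold change of 0.10 and the peptide transporter Tap1 0.40, and neither passed.

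In all, edgeR called 3 of 15531 genes, all higher in CPIP+Veh. The others, LOC103690108 and LOC103689931, carry provisional symbols with no match in the gene table used here and were named after their values were seen. LOC103690108 rose from 17.3 ± 0.83 to 93.1 ± 0.43 CPM (log2 fold change 2.42, SE 0.069, adjusted p = 0.000129) and kept its call whichever library was left out. LOC103689931 rose from 3.93 ± 2.5 to 59.8 ± 0.66 CPM (log2 fold change 3.93, SE 0.31, adjusted p = 0.0337); its log2 fold change was 3.40 without Sham+Veh 1 and 4.78 without Sham+Veh 2. Its call ended without CPIP+Veh 1 (adjusted p = 0.189), CPIP+Veh 2 (0.296), CPIP+ETA 1 (0.132) or CPIP+ETA 2 (0.112). The call of RT1-CE10 ended without Sham+Veh 1 (0.102), Sham+Veh 2 (0.207), CPIP+Veh 1 (0.165) or CPIP+Veh 2 (0.244), and the count was 1 without CPIP+Veh 2. At an unadjusted p under 0.05 there were 767 genes (364 higher, 403 lower) where chance gives 777. DESeq2 called 47 genes (32 higher, 15 lower), the same 3 among them, and limma-voom called 2. Of the 45 splits, 11 gave at least 3 genes, 2 of them real comparisons and 8 with the sham libraries parted, and the highest gave 22.

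**Figure D2:**
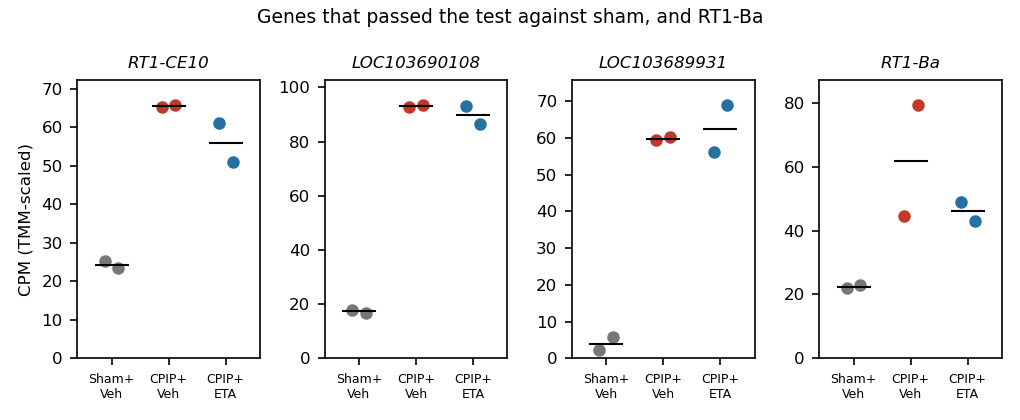
TMM-scaled CPM (y axis) of the 3 genes that passed against sham, and of RT1-Ba, in each library of the 3 groups; points are libraries and lines are means of 2. RT1-CE10 averages 24.3 CPM in sham, 65.6 in CPIP+Veh and 56 in CPIP+ETA.

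Below these, the genes with the lowest p did not pass. On the higher side were Retsat, an enzyme of vitamin A metabolism (log2 fold change 0.64, adjusted p = 0.304), the actin-capping protein Capg (0.43, 0.322), Fam134b, a receptor for turnover of the endoplasmic reticulum whose loss causes a sensory neuropathy (0.74, 0.322), and the protocadherin Pcdhb3 (1.07, 0.375). Gnb3, a G protein subunit, had 2.93 (0.375; 3.70 without Sham+Veh 1), RT1-CE3 0.56 (0.396), the copine Cpne7 1.32 (0.422), Gabra5, a GABA-A receptor subunit, 0.69 (0.425), and RT1-Ba an adjusted p of 0.44. On the lower side were the actin-severing protein Gsn (-0.75, 0.207), Zmiz2 (-1.05, 0.304), the mitochondrial protease Spg7 (-0.41, 0.304), the calpain subunit Capns1 (-0.57, 0.322), the basement membrane collagen Col15a1 (-0.73, 0.375) and the RNA-binding protein Hnrnpab (-0.40, 0.375). Acta2 and Myh11, contractile proteins of smooth muscle, had -0.98 (0.377) and -0.65 (0.477), Cdk2ap1 -0.31 (0.473) and the DNA ligase Lig4 -0.47 (0.59). DESeq2 called 16 of these 20 genes including RT1-CE10. Tnfrsf1a and Tnfrsf1b, the receptors of TNF, had -0.04 (SE 0.059) and 0.16 (SE 0.24). Tnf itself was counted only 4 to 9 times per library (38 in all) and was not tested.

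Pericyte and smooth muscle, adipocyte and endothelial markers were called lower as lists in CPIP+Veh. Pericyte and smooth muscle markers had a median of -0.22 (adjusted p = 3.44e-07, adjusted p = 0.352 with an estimated correlation), with Acta2, Myh11 and Tagln (-0.95, SE 0.25) lower adjusted over the list alone. Adipocyte markers had a median of -0.80 (adjusted p = 1.07e-06, adjusted p = 0.355 with an estimated correlation). In it the adipokine gene Adipoq was at least 12.2-fold lower (34 counts in sham and 0 in CPIP+Veh), the lipid carrier Fabp4 had -4.62 (SE 1.2) and Cfd -0.58 (SE 0.17), all 3 lower over the list alone. Fabp4 had -3.73 without Sham+Veh 1 and -3.66 without CPIP+Veh 1, and without CPIP+Veh 2 no reads were left in CPIP+Veh. The adipocyte median was -0.33 without Sham+Veh 1, -2.0 without Sham+Veh 2, -1.33 without CPIP+Veh 1, -1.84 without CPIP+Veh 2 and -1.52 without CPIP+ETA 1 or CPIP+ETA 2. Endothelial markers had a median of -0.18 (adjusted p = 5.17e-06, adjusted p = 0.763 with an estimated correlation), with Eng at -0.47 (SE 0.12), Plvap -0.78 (SE 0.22) and Kdr -0.33 (SE 0.093). Of the 18 endothelial markers 16 lay below 0 and 6 were lower at an unadjusted p under 0.05, but 0 passed over the list alone. The smooth muscle, adipocyte and endothelial lists kept their calls whichever library was left out.

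A further 7 lists were called in CPIP+Veh, and each lost its call without at least 1 library. Fibroblast and matrix genes (median -0.25, adjusted p = 2.3e-06, adjusted p = 0.763 with an estimated correlation) lost the call without CPIP+Veh 1 (-0.12). Proliferation genes (0.35, 8.04e-05, adjusted p = 0.763 with an estimated correlation) lost the call without CPIP+Veh 2 (0.13). Interferon response genes (0.23, 0.000528, adjusted p = 0.86 with an estimated correlation) lost the call without Sham+Veh 2 (0.17) or CPIP+Veh 1 (-0.15), with 0.50 without CPIP+Veh 2. Skeletal muscle markers (1.22, 0.00971, adjusted p = 0.86 with an estimated correlation) lost the call without Sham+Veh 1 (0.56) or CPIP+Veh 2 (-0.40), with 2.16 without Sham+Veh 2 and 2.00 without CPIP+Veh 1. Bone and cartilage markers (-0.22, 0.00971, adjusted p = 0.355 with an estimated correlation), of which Alpl at -0.48 was lower over the list alone, lost the call without Sham+Veh 2 (0.02) or CPIP+Veh 2 (-0.10), with -0.41 without CPIP+Veh 1 and -0.09 without CPIP+ETA 2. Immediate early genes (-0.08, 0.0158, adjusted p = 0.86 with an estimated correlation) lost the call without Sham+Veh 2 (-0.06) or CPIP+Veh 1 (0.00), with -0.17 without CPIP+Veh 2. Spinal cord markers (0.28, 0.0401, adjusted p = 0.462 with an estimated correlation) lost the call whichever of the 6 libraries was left out, at 0.27 and 0.34 without Sham+Veh 1 and 2, 0.16 and 0.18 without CPIP+Veh 1 and 2, and 0.29 without CPIP+ETA 1 or 2. In 28 of the 45 splits at least 12 lists were called.

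CPIP+ETA was compared with CPIP+Veh to find what etanercept changed in the model. Target genes of glucocorticoid hormones rose with etanercept, with a median log2 fold change of 0.38 over 18 members (camera, adjusted p = 3.06e-21, n = 2 libraries per group, adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 5 members were higher and 0 lower. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, stood at 67.5 ± 12 against 36.6 ± 0.97 CPM (log2 fold change 0.88, SE 0.12). Tsc22d3, the anti-inflammatory protein GILZ, stood at 322 ± 19 against 256 ± 7.4 CPM (0.33, SE 0.058), and Hif3a, a member of the hypoxia-inducible factor family, at 2.18 ± 0.23 against 0.152 ± 0.071 CPM (3.79, SE 0.51). The other members that passed, chosen after their values were seen, were the transcription factors Zbtb16 (1.69, SE 0.35; 1.02 without CPIP+ETA 2) and Klf9 (0.41, SE 0.10). Without CPIP+Veh 2 the median was 0.58, and without CPIP+ETA 2, in which Zbtb16 stood at 46.8 CPM against 21.4 in CPIP+ETA 1, the list kept its call. Of the 45 splits, 5 gave this list a result as strong, all with both CPIP+ETA libraries on one side and 2 of them real comparisons. In 29 splits some list was as strong as this one. In CPIP+Veh against Sham+Veh the list did not pass (median 0.02, adjusted p = 0.343), except without CPIP+Veh 1 (0.06, adjusted p = 5.97e-06).

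The macrophage list moved little with etanercept (median 0.07 over 28 members, of which 12 lay below 0, adjusted p = 0.000658, adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 4 members were higher and 0 lower, and over all genes edgeR called no member (5 at an unadjusted p under 0.05), DESeq2 3 and limma-voom 0. The haemoglobin scavenger Cd163 stood at 20.4 ± 4.8 against 6.49 ± 1.8 CPM (1.65, SE 0.23), the lectin Clec10a had 0.79 (SE 0.12) and the hyaluronan receptor Lyve1 0.97 (SE 0.16). Mrc1, the mannose receptor and the other member that passed, had 0.84 (SE 0.17) and was chosen after its value was seen. The list lost its call without CPIP+Veh 1 (median 0.03, adjusted p = 0.0834), and its median was 0.13 without CPIP+Veh 2 and 0.04 without CPIP+ETA 1. Red blood cell transcripts moved with these genes: the list had a median of 0.86 (adjusted p = 1.1e-05, adjusted p = 0.495 with an estimated correlation), and the globin Hbb was higher over the list alone (2.03, SE 0.45; 2.94 without CPIP+Veh 2). Hbb stood at 99.4 and 62.4 CPM with etanercept, 10.5 and 29.1 in CPIP+Veh, and 23.7 and 34.3 in sham. The red blood cell list kept its call whichever library was left out, with medians of 0.51 without CPIP+Veh 1 and 2.61 without CPIP+Veh 2.

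**Figure D3:**
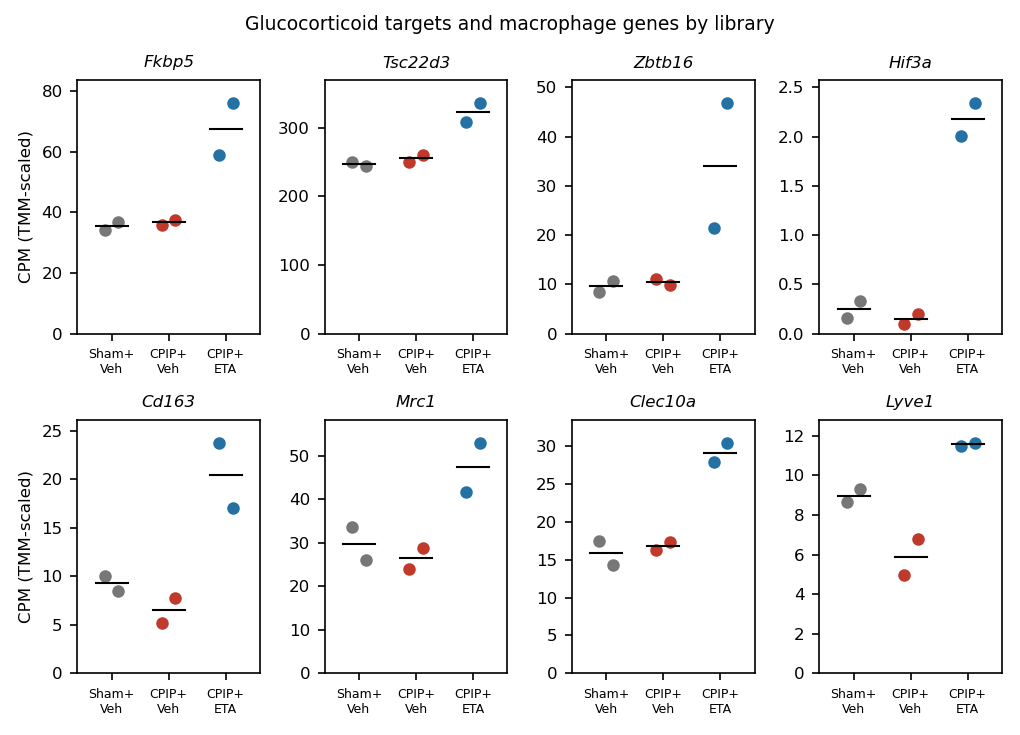
TMM-scaled CPM (y axis) of 4 glucocorticoid targets and 4 genes of the macrophage list in each library of the 3 groups; points are libraries and lines are means of 2. Both CPIP+ETA libraries lie above all 4 others for each gene, as for Fkbp5 at 59 and 76 CPM against 34.2 to 37.3. The genes were picked as higher with etanercept over their list alone, so such a separation is largely given by the choice. Against CPIP+Veh, 2 of the 18 glucocorticoid targets and 12 of the 28 macrophage genes lay below 0.

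The nerve injury genes were lower with etanercept. The list fell to a median of -0.40 (adjusted p = 3.42e-17, adjusted p = 0.495 with an estimated correlation), with 3 of 34 members above 0, and to -0.22 without CPIP+Veh 2, still called. The 3 members with the lowest p were Cckbr, a receptor of cholecystokinin (-1.84, SE 0.44), Vip (-3.26, SE 0.88) and Gal (-1.26, SE 0.34). Vip depends on the library, with 1 count in CPIP+ETA 1 and 18 in CPIP+ETA 2, and had -2.31 without CPIP+ETA 1, while without CPIP+ETA 2 the value rests on that 1 count. Atf3 and Npy, chosen after their values were seen, overlapped between the groups, while Cckbr, Vip and Gal did not. Atf3 stood at 16.2 and 42.1 CPM in CPIP+Veh and at 6.20 and 23.1 in CPIP+ETA. Npy stood at 6.08 and 35.8 CPM in CPIP+Veh and at 1.41 and 12.9 in CPIP+ETA. With edgeR 0 members passed adjusted over the list alone, 13 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0 over all genes. The CPIP+Veh libraries are part of both this comparison and the one against sham, so chance in those libraries moves the comparisons in opposite directions.

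Over all genes edgeR called 0 of 15531 for etanercept (smallest adjusted p = 0.721), with 800 at an unadjusted p under 0.05 (376 higher, 424 lower). DESeq2 called 22 (14 higher, 8 lower) and limma-voom 0. Besides Hif3a, Fkbp5, Cd163, Clec10a, Lyve1 and Tsc22d3, the genes with the lowest p on the higher side were Klf15, a glucocorticoid-induced transcription factor (0.96, SE 0.16), the actin oxidase Mical2 (0.38, SE 0.063), Ms4a6bl (0.73, SE 0.13) and Clec2l (0.34, SE 0.063). On the lower side, Anlnl1 was at least 20-fold lower (62 counts in CPIP+Veh and 0 in CPIP+ETA), and Sostdc1, a secreted antagonist of BMP and Wnt signals, had -1.16 (SE 0.18). The actin-binding protein Marcks had -0.44 (SE 0.074), the histone H3.3 gene H3f3b -0.31 (SE 0.053), and Cyp26b1, which breaks down retinoic acid, -0.67 (SE 0.12). Xkr7 had -0.77 (SE 0.14), the microglial receptor Gpr34 -1.20 (SE 0.23), the glutathione peroxidase Gpx2 -0.57 (SE 0.11), the transcription factor Ebf2 -0.55 (SE 0.11) and Nwd2 -0.53 (SE 0.11). Their adjusted p lay between 0.721 and 0.895, so none of these 20 passed with edgeR, while DESeq2 called 13 of them, among them Sostdc1 (adjusted p = 1.42e-05), Fkbp5 (4.45e-05) and Cd163 (4.92e-05). Tnfrsf1a had -0.07 (SE 0.059) and Tnfrsf1b 0.34 (SE 0.24). The TNF and NF-kB list had a median of 0.01 (adjusted p = 0.598) with etanercept and 0.03 (adjusted p = 0.375) in the model, and with etanercept it passed in opposite directions without CPIP+ETA 1 (0.21, adjusted p = 8.52e-05) and without CPIP+ETA 2 (-0.18, adjusted p = 0.0107).

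Of the 17 lists called for etanercept, the 13 not yet described each lost the call without at least 1 library. Interferon response genes (median -0.38, adjusted p = 3.39e-07, adjusted p = 0.607 with an estimated correlation) lost the call without CPIP+Veh 1 (0.04), with -0.61 without CPIP+Veh 2. Immediate early genes (0.27, 3.15e-06, adjusted p = 0.607 with an estimated correlation) had 0.51 without CPIP+Veh 2, 0.58 without CPIP+ETA 1 and -0.01, with no call, without CPIP+ETA 2. Proliferation genes (-0.35, 1.1e-05, adjusted p = 0.607 with an estimated correlation) had -0.54 without CPIP+Veh 1 and, with no call, -0.14 without CPIP+Veh 2. Antigen presentation (-0.19, 0.000509, adjusted p = 0.495 with an estimated correlation) had -0.08 without CPIP+Veh 1, -0.31 without CPIP+ETA 1 and, with no call, -0.03 without CPIP+ETA 2. Ion channels (0.08, 1.32e-05, adjusted p = 0.495 with an estimated correlation), of which 57 of 64 lay above 0, lost the call without CPIP+ETA 1 (0.01) and had 0.13 without CPIP+ETA 2. Large sensory neuron markers (0.08, 0.00477, adjusted p = 0.607 with an estimated correlation) lost it without CPIP+Veh 2 (0.04) or CPIP+ETA 1 (0.01), with 0.13 without CPIP+ETA 2. Synaptic vesicle genes (0.05, 0.0201, adjusted p = 0.746 with an estimated correlation) lost it without CPIP+Veh 1 (0.05) or CPIP+ETA 1 (-0.03), with 0.13 without CPIP+ETA 2.

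Among the markers of other cells, mast cell genes (-0.66, 0.00133, adjusted p = 0.607 with an estimated correlation), led by the protease gene Mcpt1l1 at -1.69 (SE 0.42), lost the call without CPIP+Veh 2 (-0.24) or CPIP+ETA 2 (-0.80) and had -1.07 without CPIP+Veh 1. Adipocyte markers (0.26, 0.00113, adjusted p = 0.495 with an estimated correlation) lost it without CPIP+Veh 1 (0.21) or CPIP+ETA 2 (-0.01), with 0.13 without Sham+Veh 2. Endothelial markers (0.15, 0.0022, adjusted p = 0.653 with an estimated correlation) lost it without CPIP+Veh 2 (0.10) or CPIP+ETA 2 (0.05), with 0.25 without CPIP+Veh 1 and 0.27 without CPIP+ETA 1. Fibroblast and matrix genes (-0.11, 0.00186, adjusted p = 0.653 with an estimated correlation) lost it without CPIP+Veh 2 (0.00) or CPIP+ETA 1 (0.00), with -0.26 without CPIP+Veh 1 and -0.36 without CPIP+ETA 2. Schwann cell myelin genes (-0.12, 0.00662, adjusted p = 0.746 with an estimated correlation) lost it without CPIP+Veh 1 (0.01) or CPIP+ETA 1 (0.11), with -0.24 without CPIP+Veh 2 and -0.35 without CPIP+ETA 2. The hypoxia list (0.07, 0.00267, adjusted p = 0.495 with an estimated correlation) lost it without CPIP+ETA 2 (0.03), and 3 of its members, Hif3a among them, are also glucocorticoid targets; without them it did not pass (median 0.04, adjusted p = 0.2). In 5 of the 45 splits at least 17 lists were called.

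**Figure D4:**
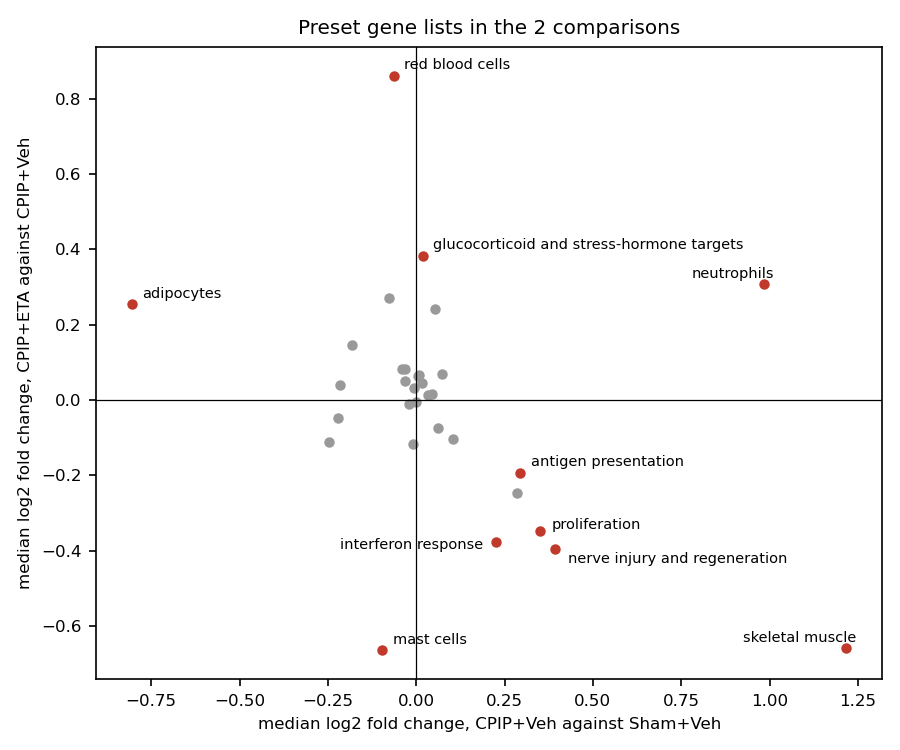
Median log2 fold change of each of the 32 gene lists in CPIP+Veh against Sham+Veh (x axis) and in CPIP+ETA against CPIP+Veh (y axis); each point is a list, with 10 lists named. The nerve injury list lies at 0.39 and -0.40, glucocorticoid targets at 0.02 and 0.38; CPIP+Veh libraries enter both axes.

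Besides TNF signalling, 8 lists were called in none of the comparisons with all libraries. Their medians with etanercept were -0.10 for cytokines and chemokines (adjusted p = 0.445, mean 0.09), 0.05 for opioid, cannabinoid and inhibitory receptors (0.844, mean -0.02), 0.03 for satellite glia (0.154) and 0.24 for lymphocytes (0.667). The complement list had -0.01 (0.692, mean 0.02), the inflammasome list -0.07 (0.445), the oxidative stress list 0.02 (0.7) and the nuclear respiratory chain -0.006 (0.716, mean 0.005). For cytokines, inhibitory receptors, complement and the respiratory chain the mean and the median thus differ in sign. With 1 library left out some passed with etanercept: cytokines without CPIP+ETA 1 (0.16, adjusted p = 0.000299) and, the other way, without CPIP+ETA 2 (-0.40, 0.0116), satellite glia without CPIP+ETA 1 (0.12, 0.000219), and lymphocytes (0.55, 0.0116) and the respiratory chain (0.04, 0.0177) without CPIP+ETA 2. By fry's test of mixed change the oxidative stress list passed in CPIP+Veh against Sham+Veh (adjusted p = 0.00696) and the hypoxia list in CPIP+ETA against Sham+Veh (adjusted p = 0.0336), while its directional test gave no adjusted p under 0.378.

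CPIP+ETA was compared with Sham+Veh to see what difference from sham was left with etanercept. Glucocorticoid targets were higher than in sham, with a median of 0.46 (camera, adjusted p = 7.27e-23, n = 2 libraries per group, adjusted p = 0.44 with an estimated correlation) and 10 members higher and 0 lower adjusted over the list alone. The 3 with the lowest p were Fkbp5 (0.92, SE 0.12), Tsc22d3 (0.38, SE 0.058) and Hif3a (3.12, SE 0.48). Further ones, chosen after their values were seen, were the clock gene Per1 (1.03, SE 0.26), the metallothionein Mt2A (1.0, SE 0.30), Ddit4 (0.76, SE 0.20), the NF-kB inhibitor Nfkbia (0.75, SE 0.17) and the kinase Sgk1 (0.58, SE 0.17). Not all of these rises were confined to etanercept. CPIP+Veh 2 came near CPIP+ETA 1 for Per1 (50.2 and 54.6 CPM), Sgk1 (43.1 and 43.9), Nfkbia (26.8 and 27.0) and Ddit4 (107 and 109). It did not for Mt2A (4.09 and 6.30 CPM). CPIP+Veh 1 stood lower for Per1 (26.5 CPM), Sgk1 (28.7), Nfkbia (18.6) and Ddit4 (71.7). The median of the list was 0.29 without CPIP+ETA 2. Macrophage markers were higher (0.16, adjusted p = 2.3e-05, adjusted p = 0.44 with an estimated correlation), with 5 members higher adjusted over the list alone, led by Clec10a (0.87, SE 0.12), Cd163 (1.14, SE 0.23) and the cathepsin Ctss (0.30, SE 0.072). Red blood cell transcripts were higher too as a list (1.13, adjusted p = 0.000158, adjusted p = 0.535 with an estimated correlation, 0.66 without Sham+Veh 2). Of their 10 members 9 lay above 0 and 2 were higher at an unadjusted p under 0.05, but 0 passed over the list alone. These 3 lists kept their calls whichever library was left out.

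Collagen and matrix genes were lower in CPIP+ETA than in sham. The fibroblast list had a median of -0.37 (adjusted p = 5.34e-14, adjusted p = 0.535 with an estimated correlation), and 4 of 26 members were lower adjusted over the list alone, the fibrillar collagens Col3a1 (-0.59, SE 0.13), Col1a1 (-0.68, SE 0.16) and Col1a2 (-0.49, SE 0.13) and the microfibrillar collagen Col6a1 (-0.38, SE 0.098). Its median was -0.18 without CPIP+ETA 1 and -0.56 without CPIP+ETA 2, and it kept its call throughout. Nerve injury genes did not pass as a group against sham (median 0.00, mean 0.33, adjusted p = 0.076), except without CPIP+ETA 1 (0.08, adjusted p = 0.00155), with Atf3 at 6.20 and 23.1 CPM in the CPIP+ETA libraries. The same 3 genes as in CPIP+Veh were called by edgeR: LOC103690108 (2.37, adjusted p = 0.000149), LOC103689931 (3.99, adjusted p = 0.0404) and RT1-CE10 (1.21, adjusted p = 0.0404, 56 ± 7.1 CPM). LOC103690108 kept its call whichever library was left out. LOC103689931 lost it without CPIP+Veh 1 (0.163), CPIP+Veh 2 (0.164), CPIP+ETA 1 (0.129) or CPIP+ETA 2 (0.115), with log2 fold changes of 3.46 without Sham+Veh 1 and 4.85 without Sham+Veh 2. RT1-CE10 lost it without any library but CPIP+ETA 2, with adjusted p of 0.183 (Sham+Veh 1), 0.374 (Sham+Veh 2), 0.163 (CPIP+Veh 1), 0.164 (CPIP+Veh 2) and 0.0706 (CPIP+ETA 1). The count was 1 without CPIP+Veh 1, CPIP+Veh 2 or CPIP+ETA 1, and 1 with limma-voom or with only the 2 groups in the fit, while DESeq2 called 45 (21 higher, 24 lower). At an unadjusted p under 0.05 there were 990 genes (410 higher, 580 lower).

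The genes with the lowest p against sham that did not pass were, on the higher side, Retsat (0.67, SE 0.083, adjusted p = 0.256), Fkbp5, Clec10a and Tsc22d3 (adjusted p = 0.262, 0.27 and 0.315). On the lower side were Hnrnpab (-0.57, adjusted p = 0.17), Ebf2 (-0.90, 0.256), Cyp26b1 (-0.91, 0.262), Gsn (-0.65, 0.262) and Capns1 (-0.57, 0.27). Tnfrsf1a had -0.11 (SE 0.059, adjusted p = 0.83) and Tnfrsf1b 0.50 (SE 0.24, adjusted p = 0.813). The other called lists each lost the call without at least 1 library. Pericyte and smooth muscle markers (-0.31, adjusted p = 0.000505, adjusted p = 0.44 with an estimated correlation) lost it without CPIP+ETA 1 (-0.18). Antigen presentation (0.24, 0.00115, adjusted p = 0.535 with an estimated correlation) lost it without Sham+Veh 2 (0.17) or CPIP+ETA 1 (0.12). Hypoxia genes (0.04, 0.00109, adjusted p = 0.44 with an estimated correlation) lost it without CPIP+ETA 2 (0.05) and without the 3 glucocorticoid targets (adjusted p = 0.0761), with 0.07 without Sham+Veh 2. Mast cell markers (-0.62, 0.00252, adjusted p = 0.554 with an estimated correlation), of which Mcpt1l1 at -1.95 passed over the list alone, lost it without Sham+Veh 2 (-0.57) or CPIP+ETA 2 (-0.82), with -1.20 without Sham+Veh 1 and -1.03 without CPIP+ETA 1. Neutrophil markers (1.23, 0.00286, adjusted p = 0.547 with an estimated correlation) lost it without CPIP+ETA 2 (0.52), with 1.86 without CPIP+ETA 1. Bone markers (-0.22, 0.0124, adjusted p = 0.44 with an estimated correlation) lost it without Sham+Veh 2 (-0.04), CPIP+ETA 1 (-0.34) or CPIP+ETA 2 (-0.18), with -0.14 without Sham+Veh 1. Schwann cell myelin (-0.10, 0.0313, adjusted p = 0.78 with an estimated correlation) lost it without Sham+Veh 2 (0.06) or CPIP+ETA 1 (0.09), with -0.25 without Sham+Veh 1 and -0.37 without CPIP+ETA 2. Nociceptor markers (0.10, 0.0355, adjusted p = 0.535 with an estimated correlation) lost it without Sham+Veh 2 (0.07) or CPIP+ETA 2 (0.04), and ion channels (0.06, 0.0355, adjusted p = 0.768 with an estimated correlation) without Sham+Veh 2 (0.04) or CPIP+ETA 1 (-0.01), with 0.12 without CPIP+ETA 2.

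Genes changed in the model and moved back by etanercept were sought across both comparisons. With edgeR 0 genes were called in opposite directions, since 3 were called in the model and 0 with etanercept (767 and 800 at an unadjusted p under 0.05). DESeq2 called 4 genes in opposite directions, Wbp11l1, Pot1b, LOC685668 and LOC686087, and limma-voom called 0. These 4 were chosen after their values were seen. With the libraries regrouped in all 45 ways, 33 regroupings gave at least 4 such genes with DESeq2 (median 6, highest 21), a count also chosen after the result was seen. The regrouping with 21 keeps the sham libraries together and so holds the difference from sham. A regrouping that parts them still gave 17, so chance cannot be excluded. Across genes the log2 fold changes of the comparisons correlated at -0.4734, and unchanged groups sharing the CPIP+Veh libraries gave -0.4948 on average over 100 simulations (range -0.544 to -0.4345). The covariance was -0.0524 against -0.0444 in the simulations (-0.052 to -0.0372), a difference of -0.008. With a separate CPIP+Veh library on each side the correlations were 0.0057 and 0.0162 and the covariances 9e-04 and 0.0027, so neither showed a reversal. With the libraries shared, the correlation lay within the simulated range and the covariance below the lowest simulated value. The simulation drew genes independently of each other, so its range may be too narrow and the difference of -0.008 decides nothing. These values are across genes, which are not independent replicates.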

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

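DESeq2 on the named genes and the changes to list membership were chosen only after the results were seen; the other alternatives were not. The 3 genes called against sham were the same under RLE, upper-quartile and library-total scaling, without the filter, at 1 CPM in 2 libraries, at a log2 fold change of at least 1 and at an adjusted p under 0.1, in both comparisons with sham. The robust prior left 2 of them in each, and limma-voom or the fit of only the 2 groups left 2 for CPIP+Veh against Sham+Veh. With DESeq2 the counts became 47, 22 and 45 genes for CPIP+Veh against Sham+Veh, CPIP+ETA against CPIP+Veh and CPIP+ETA against Sham+Veh, and 4 genes in opposite directions; the cause was not tested. For CPIP+ETA against Sham+Veh limma-voom and the fit of only the 2 groups each gave 1, the latter with fewer samples. Leaving out 1 library gave 1 to 3 genes for CPIP+Veh against Sham+Veh, 1 to 2 for CPIP+ETA against Sham+Veh and 0 for etanercept. With an estimated correlation 0 lists were called in each comparison instead of 12, 17 and 13 (smallest adjusted p = 0.352, 0.495 and 0.44), so every list result rests on the preset correlation of 0.01. With only members of at least 1 CPM, 12, 15 and 12 lists were called. In CPIP+ETA against Sham+Veh 11 of the 13 calls were kept that way. Without members at 0 in a group the counts stayed at 12, 17 and 13. Leaving out 1 library turned camera's direction, with a call before or after, in these lists, whose lowest and highest medians over the 6 fits were, for CPIP+Veh against Sham+Veh, Schwann cell myelin (-0.148 to 0.158), red blood cells (-1.247 to 0.523), interferon response (-0.154 to 0.503) and skeletal muscle (-0.398 to 2.158). For CPIP+ETA against CPIP+Veh they were fibroblasts (-0.364 to 0.002), skeletal muscle (-2.643 to 1.039), cytokines (-0.403 to 0.163), Schwann cell myelin (-0.351 to 0.113), synaptic vesicles (-0.028 to 0.134) and TNF signalling (-0.178 to 0.207), and for CPIP+ETA against Sham+Veh Schwann cell myelin (-0.367 to 0.087), ion channels (-0.008 to 0.115) and synaptic vesicles (-0.046 to 0.102). Of the other called lists the median alone changed sign for bone and cartilage in CPIP+Veh against Sham+Veh (0.02 without Sham+Veh 2) and, with etanercept, for interferon response (0.04 without CPIP+Veh 1), immediate early genes and adipocytes (both -0.01 without CPIP+ETA 2). Fewer samples enter these fits, and which library decides each is given beside the result where the list was called. Over all alternatives, named genes kept direction and side of the threshold in 3188 values, gained a call in 46, lost one in 17, turned with a call before or after in 0 and turned with no call in 19, and lists did so in 856, 40, 92, 15 and 56. Nearly all named genes had no call with all libraries, so their unchanged values say little about stability. The 17 losses could come only from the 3 genes called against sham. The title numbers 1 and 2 showed no pairing across all genes: deviations from the group means correlated at 0.035, -0.106 and 0.05 between same-numbered libraries. With the number as a replicate block edgeR called 3, 0 and 3 genes and camera 12, 19 and 14 lists. These correlations cannot exclude a difference shared by some genes. The split of CPIP+Veh 1 and CPIP+ETA 1 against CPIP+Veh 2 and CPIP+ETA 2 called 19 lists, the highest count, with skeletal muscle the strongest. Depth limits low genes such as Tnf, at 4 to 9 counts per library. In the simulation of CPIP+Veh against Sham+Veh 38.8% of genes changed 1.5-fold were recovered, a share that the real libraries may not reach.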

Other observations

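The tests of RT1 genotype, of the class I sum, of the nerve injury pattern, of blood content and of the strongest list were chosen only after the results were seen, and so were the genes of this paragraph. DESeq2 called further genes against sham in CPIP+ETA, which edgeR did not. Lower were the matrix proteins Thbs4 (log2 fold change -0.68, DESeq2 adjusted p = 0.000301) and Bgn (-0.77, 0.0173), the hedgehog receptor Ptch1 (-0.82, 0.00031), the pericyte transcription factor Tbx18 (-1.09, 0.0298), the caveolar protein Cav1 (-0.62, 0.0298) and the secreted factor Serpinf1 (-0.57, 0.0475). The clock gene Per1 was higher (1.03, 0.0331). In CPIP+Veh against Sham+Veh, DESeq2 alone called the annexin Anxa8 (1.33, 0.000217), the neuronal tubulin Tubb2b (0.33, 0.000633), the membrane glycoprotein Gpm6a (0.80, 0.00281) and the vesicle protein Syt4 (adjusted p = 0.0024) higher, all at n = 2 libraries per group.

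Several RT1 class I genes were higher in the CPIP libraries than in sham, with RT1-CE10 at a log2 fold change of 1.21 in CPIP+ETA. Induction of the whole class I pathway by about as much as RT1-CE10 is argued against. The 8 partners B2m, Tap1, Tap2, Tapbp, Psmb8, Psmb9, Psmb10 and Nlrc5 had a median of -0.01 (SD 0.14) in the same comparison. In CPIP+Veh against Sham+Veh their median was 0.09 (SD 0.15, Tap1 highest at 0.40), where RT1-CE10 had 1.43. RT1-CE10 was picked as a called gene, and the class I genes summed rose by a log2 ratio of only 0.23. A smaller rise shared by the pathway stays open. Reads moved between near-identical class I genes stay open. The summed CPM of all 27 RT1 genes was higher by a log2 ratio of 0.39, but this sum holds 9 class II genes that were higher themselves. Over the 18 class I genes the ratio was 0.23, with CPIP+ETA 2 (503 CPM) below Sham+Veh 1 (523 CPM). A candidate explanation is another RT1 haplotype in the CPIP animals than in sham: RT1-CE10 spanned 0.37 over the 4 CPIP libraries and stood 1.31 from sham. The gene was picked as called in both CPIP groups, so a range below that distance is largely given by the choice and decides nothing. Genotype and group cannot be told apart in this design. An effect of the model on these genes stays open beside it.

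Nerve injury genes were higher in CPIP+Veh and lower with etanercept. The list was still lower without CPIP+Veh 2 (median -0.22), so for the list as a whole CPIP+Veh 1 also stood above CPIP+ETA. Members differed: CPIP+ETA 2 lay above CPIP+Veh 1 for Atf3 (23.1 and 16.2 CPM) and Npy (12.9 and 6.08), and below it for Cckbr, Vip and Gal. With 1 library left in the group this fit cannot exclude that single libraries explain the pattern. Splits that part the CPIP+Veh libraries also gave this list a camera -log10 p of up to 15.8. A lower share of neuronal RNA does not account for the pattern, since large sensory neuron markers had a median of 0.08 (SD 0.1) with etanercept. The CPIP+Veh libraries stand on both sides, and with a separate CPIP+Veh library on each side the covariance over the members was -0.955 (SE 0.42) or -0.66 (SE 0.36), which leaves open whether the libraries that happened to hold more injury RNA explain both changes. The 2 of 45 splits with this list as strong (-log10 p of 24.46 for the real split and 28.88 for the highest other) both keep the CPIP+Veh libraries on one side, which decides nothing about chance, while for the strongest list of the model comparison chance cannot be excluded (20 of 45, highest other 48.45). Less injury response with etanercept is a biological reading that stays open beside these.

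Glucocorticoid targets were higher with etanercept, in both CPIP+ETA libraries for Fkbp5, Tsc22d3, Zbtb16 and Hif3a. Another time of day at dissection may contribute: the median of 8 clock output genes minus that of 4 opposite-phase genes was -0.39 (exact two-sided p = 0.0768, 495 permutations of the gene labels). This p takes the genes as independent and does not measure the spread between libraries. All 8 outputs lay below 0 and, of the others, Npas2 stood at 0.63, Arntl at 0.36, Clock at 0 and Cry1 at -0.28. Left out of the sets were Dbp (-0.96), whose value had been seen before, and Per1 (0.49), a member of the glucocorticoid list. More blood in the tissue also stays open, since haemoglobin was 1.91 higher in library 2 than in library 1 of CPIP+Veh and the list 0.22 higher (SE 0.11), where 0.36 would be needed. A response to etanercept itself, or different stress at sampling, was not tested. The 5 of 45 splits with this list as strong (22.02 in the real split, 36.22 in the highest other) all keep both CPIP+ETA libraries on one side and so carry the same difference, which decides nothing about chance, while for the strongest list of this comparison chance cannot be excluded (29 of 45, highest other 48.45).

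Splitting the 6 libraries into pairs in all 45 ways showed how much the libraries differ whatever their labels. The counts of splits include the real comparisons. For the number of lists called chance cannot be excluded in any comparison: 28 splits gave at least the 12 lists of CPIP+Veh against Sham+Veh, 5 at least the 17 of CPIP+ETA against CPIP+Veh and 20 at least the 13 of CPIP+ETA against Sham+Veh, and the highest was 19 in each. For the 3 genes called in CPIP+Veh against Sham+Veh 11 splits gave as many, 8 of them with the sham libraries parted, so chance cannot be excluded for this count, which says nothing of a single gene. The highest called 22 genes, but it sets the sham libraries against CPIP+Veh 1 and CPIP+ETA 1 and so holds the difference from sham. The highest with the sham libraries parted called 10, which points to differences between samples beside the groups.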
